A study of Mus musculus with 6 samples.

How the data were processed

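Total RNA of 6 sorted cell samples was measured, 3 of c-kit-positive and 3 of c-kit-negative cells of the CD31-positive, CD45-negative, Ter119-negative gate, with 1 array each. Per the labels' protocols, tissue was digested with collagenase and stained with antibodies before the sort. Per the labels' protocols, 5 ng of total RNA of each sample was amplified with a whole-transcript kit (NuGEN Ovation Pico), turned into sense-strand cDNA, fragmented and labelled with biotin. Amplification from so little RNA can compress or distort ratios between transcripts, and array background compresses the fold changes of dim genes.

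The values are log2 values made by the authors with RMA, per the submitters' processing notes, a method that subtracts background, equalises the arrays' distributions and summarises probes into probe sets. The version, the background settings and the level of summary are not given in the sources used here. The log2 scale was read from the values, which ran from 1.22 to 13.7 with near-equal quartiles on all arrays. No 2 arrays held identical values. The table carries no detection calls, so no level below which a gene is background was set, and no gene is called absent.

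The table held 34760 probe sets. The annotation table of the platform gave 1 gene symbol for 21640 of them and several for 1321, and did not list 11799, which stayed unnamed here. Of the 21640 probe sets with 1 symbol, 21553 matched the reference gene table by Entrez identifier, and 0 symbols changed. They covered 19937 genes. For the 954 genes with more than 1 probe set, the probe set with the highest mean over all 6 arrays was used. Among the genes named by the rule given below, Mecom and Zfp640 had 2 probe sets each. Their differences were -2.50 and -0.93 for Mecom and 2.11 and 1.66 for Zfp640. Genes named outside that rule were not checked for further probe sets. No genome was used here, so no positions are given. List members without a probe set of 1 gene were not analysed here.

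Groups were taken from the labels. The populations were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter on level, no block), with Benjamini-Hochberg adjustment over all 19937 genes and a threshold of adjusted p under 0.05. Values are given as group mean ± SD with n = 3, and differences as c-kit-positive minus c-kit-negative with the SE from limma. An exact permutation test of 3 against 3 values has a smallest p of 0.1, so none was run for single genes. The test was checked on simulated arrays of the 19937 genes for this comparison, with 50 genes changed at each size. It recovered 2% of genes changed by 0.5 on the log2 scale, 42% of those changed by 1, 94% by 2 and 100% by 3. Of 127 genes called there 8 were unchanged, and a list shifted on purpose was called while 0 of the other lists were. Fewer genes were called there than the 1477 of the data, and the adjustment is stricter when fewer genes change. The shares recovered there are thus not those of the real comparison. The simulated genes varied independently of each other. The check therefore cannot show how often camera calls lists whose genes vary together, as those of the macrophage list did (estimated correlation 0.49).

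The design, the alternatives, 26 gene lists and the rule for named genes were fixed before the data were examined. The rule names the genes of the sort gate and Cdca7 as values, the 12 largest differences in each direction among genes past the threshold whose groups did not overlap, and from each list up to 4 members past the threshold with the smallest p, or where none passed the member of smallest p as values. It leaves out gene models known only by a number or clone name, microRNAs and small nucleolar RNAs. Of the lists, 24 were tested with camera (preset correlation 0.01), adjusted over the 24 lists, and again with an estimated correlation and with fry. The genes of the sort gate and the sex-linked genes were not tested as sets. Counts adjusted over the list alone apply Benjamini-Hochberg within each list.

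Alternatives were median centring, quantile normalization, leaving out the dimmest 30 or 50 percent of genes, other ways of combining probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, stricter thresholds, all probe sets, a linear model without variance moderation, and leaving out each array in turn. All 10 splits of the 6 arrays into 3 and 3 were fitted as well. Figures were drawn with matplotlib.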

Results

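The series profiled cells of the aorta, gonad and mesonephros (AGM) region of CD1 mouse embryos at E11.5 (E, embryonic day). This region holds the dorsal aorta, whose wall gives rise to the earliest definitive haematopoietic stem cells, and the genital ridges, which primordial germ cells colonise. Digested tissue was sorted for cells that carried CD31, the product of Pecam1, and lacked both the leukocyte antigen CD45, the product of Ptprc, and the red cell antigen Ter119. The sorted cells were divided by surface c-kit, the receptor for stem cell factor, into a c-kit-positive and a c-kit-negative population. Each population was measured on 3 arrays, 6 in all. The labels call the replicates biological and do not say how embryos were pooled, so single-gene p-values measure the spread between these arrays. Camera p-values compare a list's genes with all other genes at a preset correlation, so their size does not measure that spread. Values ran from 1.22 to 13.7 on the log2 scale, with array medians between 5.42 and 5.52, and the number of arrays limits the precision. Across genes, which are not independent replicates, arrays of 1 population correlated at 0.957 to 0.964 and arrays of different populations at 0.937 to 0.948. The leading principal component carried 55.3% of the variance and placed the c-kit-negative arrays between -36.1 and -34.4 and the c-kit-positive arrays between 32.5 and 36.7.

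The comparison asked how c-kit-positive cells, the fraction in which haematopoietic progenitors emerge, differ from the c-kit-negative cells of the same CD31 gate. Endothelial genes were far lower in c-kit-positive cells: all 25 measured pan-endothelial genes fell, among them Kdr, the main receptor for vascular endothelial growth factor, at 4.93 ± 0.23 against 9.80 ± 0.16 (log2, SD, n = 3 each, 29.3-fold lower). Primordial germ cell markers were higher: 21 of 27 rose, led by Sycp3, a component of the synaptonemal complex of meiosis, at 7.48 ± 0.16 against 4.99 ± 0.34 (SD, n = 3 each, 5.59-fold). Haematopoietic genes divided, with Myb, a transcription factor of definitive progenitors, 3.40-fold higher and Mecom, a stem cell transcription factor also made by endothelium, 5.64-fold lower. Of 16 imprinted genes 12 fell and 1 rose, with Mest the most changed at 25.3-fold lower.

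Of 19937 genes, 540 were higher and 937 lower in c-kit-positive cells at a Benjamini-Hochberg adjusted p under 0.05 in limma. The falls were the larger changes: 615 of the 937 were at least 2-fold (median 2.29-fold), 189 exceeded 4-fold and 52 exceeded 8-fold. Of the 540 rises, 215 were at least 2-fold (median 1.84-fold), 12 exceeded 4-fold and none exceeded 8-fold. The 3 values of one population all lay beyond the 3 of the other for 5344 genes, or 26.8%, where chance gives 10%. With 1 array left out the count of higher genes was 276 without c-kit-negative replicate 1, 292 without replicate 2 and 323 without replicate 3 of that population, and 311 and 287 without c-kit-positive replicates 1 and 3. The linear model without variance moderation called 66 genes higher and 216 lower.

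**Figure D1:**
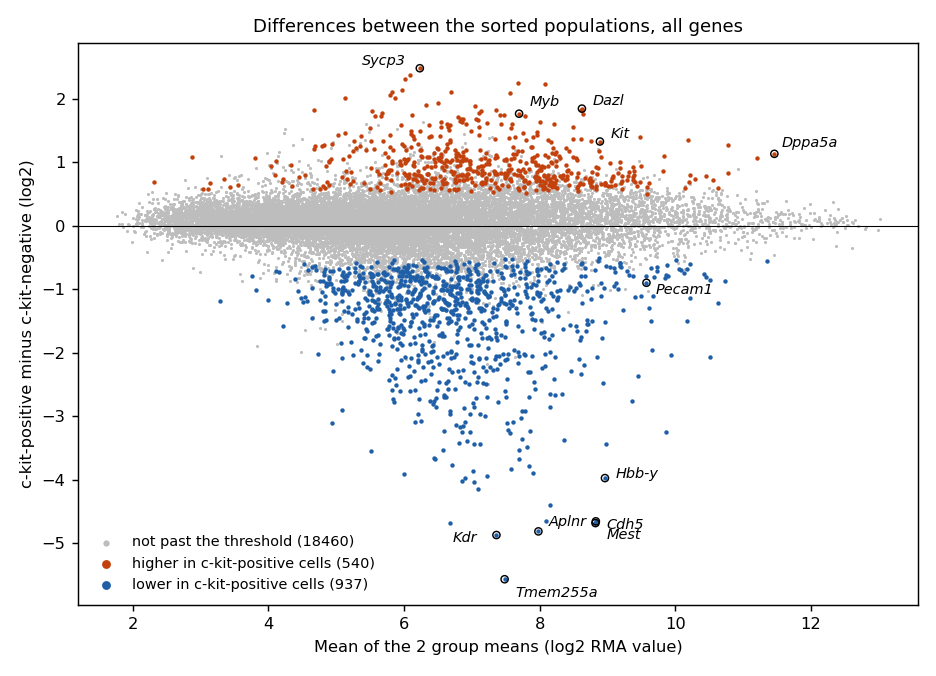
Each point is 1 of the 19937 genes, with the mean of both population means on the horizontal axis and the difference between c-kit-positive and c-kit-negative cells on the vertical axis, both on the log2 scale; coloured points passed an adjusted p under 0.05 in limma (540 higher, 937 lower). The lowest labelled gene, Tmem255a, lies at -5.57, and the highest, Sycp3, at 2.48.

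The genes of the sort gate came out as follows. Kit (probe set 10522530) was at 9.55 ± 0.03 in c-kit-positive and 8.22 ± 0.04 in c-kit-negative cells (SD, n = 3 each), a difference of 1.33 ± 0.12 (SE, adjusted p = 0.000453, limma). The populations were separated on its protein, so this difference checks the labels and is not a finding. Pecam1 (probe set 10392221), whose protein both populations were selected for, was lower by 1.86-fold in c-kit-positive cells (9.13 ± 0.16 against 10.02 ± 0.02, adjusted p = 0.00597, limma). Ptprc, whose protein was selected against, was at 8.52 ± 0.13 and 8.75 ± 0.60 (adjusted p = 0.689, limma), and the c-kit-negative arrays stood at 9.40, 8.66 and 8.21 in replicates 1, 2 and 3. Cdca7, known from work on Notch targets in this region, was at 8.69 ± 0.27 in c-kit-positive and 8.28 ± 0.28 in c-kit-negative cells, a difference of 0.41 ± 0.20 (SE) that did not pass (adjusted p = 0.285, limma).

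The largest falls were those of Tmem255a, at 4.70 ± 0.13 against 10.27 ± 0.07 (SD, n = 3 each, 47.5-fold lower, adjusted p = 1.17e-06, limma), and of Kdr. Next came Aplnr, the apelin receptor of venous endothelium (28.2-fold lower), Cdh5, which encodes VE-cadherin (25.7-fold), Klhl4 (25.7-fold), Mest and the sialomucin gene Emcn (25.1-fold). Sparcl1 was 21.1-fold lower, the growth factor binding protein gene Igfbp3 17.8-fold, the laminin gene Lama4 16.4-fold, the semaphorin and VEGF co-receptor Nrp1 16.3-fold and the embryonic globin Hbb-y 15.7-fold. After Sycp3, the largest rises were those of Dapl1 (5.21-fold), Ccnb1ip1, a regulator of meiotic crossovers (4.98-fold), Epp13 (4.77-fold), Lrrc34 (4.73-fold) and Zfp640 (4.33-fold). Car1, a carbonic anhydrase of red cells, rose by 4.32-fold and Atf7ip2 by 4.16-fold. Smc1b, a cohesin subunit of meiosis, was 4.05-fold higher, Asz1, a germ line gene of piRNA production, 4.04-fold, Prdm14, a transcription factor of germ cell specification, 3.83-fold, and Fam169a 3.69-fold. The rise of Lrrc34 was 2.88-fold without c-kit-negative replicate 2. The rule that named these genes required the 3 values of each population to lie beyond those of the other, so their separation is not a further result.

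Endothelial genes were described by 3 lists. All 25 measured pan-endothelial genes fell over all genes tested and also when adjusted over the list alone, by a median of 2.23 on the log2 scale, or 4.69-fold (camera in limma, adjusted p = 7.40e-42). Tek, the angiopoietin receptor, was 10.9-fold lower and Sox18, a transcription factor of vessel and lymphatic development, 6.49-fold lower. The smallest fall in the list was that of Nos3, named after its value was seen, with a difference of -0.72. Of 21 arterial genes 15 fell, or 17 adjusted over the list alone (median -1.22, camera adjusted p = 1.94e-19, limma). Efnb2, the arterial ephrin, fell by 2.46 ± 0.16 and Gja5, an arterial connexin, fell by 3.78 ± 0.34 (log2, SE), and Hey2, an effector of Notch in arteries, was 3.61-fold lower. Of 14 venous and lymphatic genes 9 fell, and 10 fell and 1 rose adjusted over the list alone (median -1.33, camera adjusted p = 7.51e-13, limma). Nr2f2, a determinant of venous identity, was 5.05-fold lower, Nrp2 9.38-fold and the scavenger receptor gene Stab1 4.06-fold. On the same arrays the markers of mesenchyme and smooth muscle were also lower, by a median of -1.07.

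**Figure D2:**
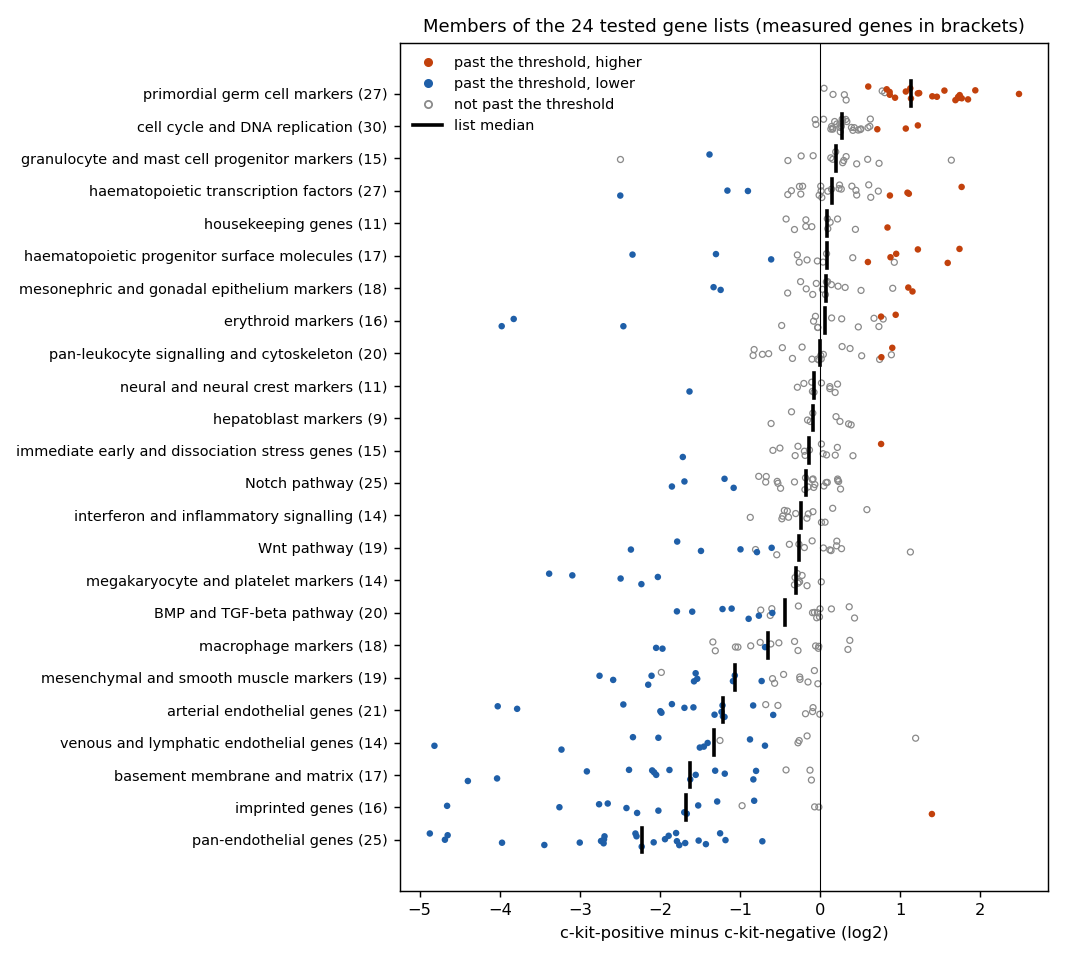
Each point is a measured member of 1 of the 24 tested gene lists, placed by its difference between c-kit-positive and c-kit-negative cells (log2); filled points passed an adjusted p under 0.05 in limma, open points did not, and the bar is the list's median. The pan-endothelial genes lie lowest (median -2.23) and the primordial germ cell markers highest (median 1.13).

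Matrix genes fell on the same arrays as the pan-endothelial genes and the mesenchymal markers (medians -2.23 and -1.07). Of 17 basement membrane and matrix genes 14 fell, the same number as when adjusted over the list alone, and none rose (median -1.62, camera adjusted p = 3.26e-22, limma). The nidogen gene Nid1 was 7.53-fold lower, the perlecan gene Hspg2 4.28-fold and the laminin gene Lamb1 4.13-fold. The 3 signalling lists below share 7 (Notch), 2 (BMP and TGF-beta) and 0 (Wnt) of their genes with other lists.

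Of 25 measured genes of the Notch pathway 4 fell, or 8 adjusted over the list alone, and none rose (median -0.18, camera adjusted p = 6.58e-05, limma). They were Hey2, the ligands Dll4 (2.29-fold lower) and Jag1 (3.24-fold lower), which with Hey2 also stand in the arterial list, and Adam10, a protease that cleaves Notch receptors (2.11-fold lower). Of 20 genes of the BMP and TGF-beta pathway 7 fell, and 9 fell and 1 rose adjusted over the list alone (median -0.43, camera adjusted p = 2.16e-05, limma). Among them were the endothelial co-receptor Eng (3.45-fold lower), the receptors Bmpr2 (2.15-fold) and Acvrl1 (2.33-fold) and the ligand Bmp4 (3.03-fold). Without c-kit-positive replicate 1 or 3, or c-kit-negative replicate 1 or 3, only 4 fell over all genes. Of 19 genes of the Wnt pathway 6 fell, and 8 fell and 1 rose adjusted over the list alone (median -0.26, camera adjusted p = 0.000423, limma). They included the nuclear effector Tcf7l2 (3.45-fold lower), the receptor Fzd4 (5.14-fold), beta-catenin, Ctnnb1 (1.73-fold), and the secreted inhibitor Sfrp1 (2.80-fold). The pan-endothelial genes stood lower on the same arrays by a median of -2.23.

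Imprinted genes, expressed from only the maternal or the paternal copy, were among the most changed. Of 16 measured, 12 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone (median -1.68, camera adjusted p = 4.42e-17, limma). Mest was at 6.50 ± 0.26 against 11.16 ± 0.09 (SD, n = 3 each). Peg10 was 9.55-fold lower, the growth factor Igf2 6.78-fold and the growth inhibitor Grb10 4.88-fold. The member that rose, Phlda2, named after its value was seen, was 2.63-fold higher and did not pass without c-kit-negative replicate 2. On the same arrays pan-endothelial genes were lower and germ cell markers higher, by medians of -2.23 and 1.13.

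Of 27 measured primordial germ cell markers 21 rose, or 23 adjusted over the list alone, and none fell (median 1.13, 2.20-fold, camera adjusted p = 5.02e-19, limma). With an estimated correlation the camera adjusted p was 0.0236 (limma). The rises numbered 14 without c-kit-positive replicate 1 or 3 and 20 without replicate 2 of that population. Without c-kit-negative replicates 1, 2 and 3 they numbered 15, 16 and 17. All 27 had the higher mean in c-kit-positive cells. Dazl, an RNA-binding protein of germ cells, rose by 3.60-fold (adjusted p = 0.000267, limma) and Ddx4, the germ line helicase, by 3.23-fold (adjusted p = 0.000389, limma). Dppa5a was at 12.03 in c-kit-positive and 10.89 in c-kit-negative cells (adjusted p = 0.0235, limma), and Rhox9 at 11.74 and 10.67 (adjusted p = 0.00705, limma), both named after their values were seen.

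**Figure D3:**
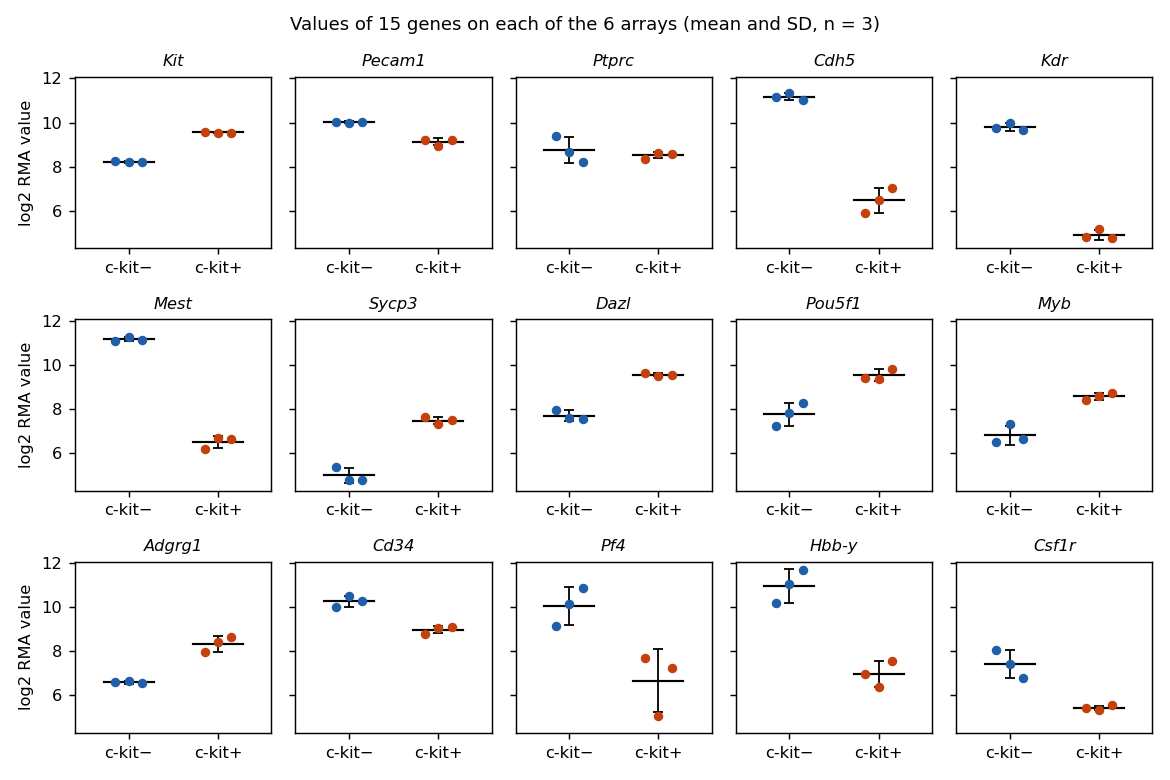
The log2 values of 15 genes on each array, with c-kit-negative arrays in blue, c-kit-positive arrays in orange, and the mean with its SD (n = 3) in black. Cdh5, Kdr and Mest stand lower and Sycp3, Dazl, Pou5f1, Myb and Adgrg1 higher in all 3 c-kit-positive arrays than in any c-kit-negative array, while Ptprc overlaps.

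Haematopoietic genes did not move together. Of 27 transcription factors 4 rose and 3 fell, or 7 and 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.567, limma). Myb was at 8.58 ± 0.16 against 6.81 ± 0.42 (SD, n = 3 each, adjusted p = 0.00208, limma), and Hlf, a factor of haematopoietic stem cells, was 2.16-fold higher. Mecom fell by 2.50 ± 0.32 and Erg, an ETS factor of both blood and endothelium, fell by 1.16 ± 0.18 (log2, SE). Runx1, the factor required for stem cell emergence and named here after its value was seen, differed by 0.40 with an adjusted p of 0.246 (limma). Only 2 factors rose without c-kit-positive replicate 2, or c-kit-negative replicate 2 or 3. Of 17 progenitor surface molecules 6 rose and 3 fell, the same counts as when adjusted over the list alone (median 0.08, camera adjusted p = 0.695, limma). The adhesion receptor Adgrg1 (GPR56) was 3.34-fold higher and the cytokine receptor Flt3 1.84-fold higher, whereas Cd93 was 5.07-fold and Cd34 2.46-fold lower, 2 molecules that endothelium also carries. The 6 rises became 3 without c-kit-positive replicate 3, or c-kit-negative replicate 1 or 2, and 2 without c-kit-negative replicate 3. Of 20 pan-leukocyte genes 2 rose, the GTPase Rac2 (1.70-fold) and its activator Dock2 (1.87-fold), or 5 rose and 3 fell adjusted over the list alone. The list's median was -0.0033 and its mean 0.02, while camera pointed down (adjusted p = 0.932, limma). With 1 array left out the mean ran from -0.05 to 0.13. Of its 2 rises 1 was left without c-kit-positive replicate 1 or 2, or c-kit-negative replicate 2 or 3. On the same arrays germ cell markers were higher by a median of 1.13.

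Markers of other blood cells were also measured; the gate selects against CD45 and Ter119, while platelets carry CD31. Of 16 erythroid markers 3 fell and 2 rose, or 3 and 4 adjusted over the list alone, with a median of 0.06, a mean of -0.38 and a camera test that pointed down (adjusted p = 0.932, limma). The falls were embryonic globins, Hbb-y, Hba-x (14.2-fold lower) and Hbb-bh1 (5.49-fold lower), and the transferrin receptor Tfrc was 1.69-fold higher. The 2 rises became 0 without c-kit-positive replicate 3, or c-kit-negative replicate 1 or 2, and 1 without c-kit-positive replicate 2 or c-kit-negative replicate 3. Of 14 megakaryocyte and platelet markers 5 fell and none rose, the same number as when adjusted over the list alone (median -0.30, mean -1.09, camera adjusted p = 3.94e-06, limma). With an estimated correlation the list did not pass (adjusted p = 0.18 with an estimated correlation). The platelet chemokines Pf4 and Ppbp were 10.4-fold and 8.54-fold lower, and Thbs1 (4.70-fold) and Gng11 (5.62-fold), which endothelium also expresses, fell too. Pf4 was 5.96-fold lower without c-kit-positive replicate 2, and Ppbp 13.7-fold lower without c-kit-negative replicate 1. Only 3 fell without c-kit-positive replicate 1, or c-kit-negative replicate 2 or 3. Of 18 macrophage markers 3 fell, or 6 adjusted over the list alone (median -0.65, camera adjusted p = 9.65e-05, limma), and the list did not pass with an estimated correlation (adjusted p = 0.38 with an estimated correlation). These were Csf1r, the receptor of macrophage colony-stimulating factor (3.91-fold lower), the protease Ctss (4.14-fold) and the adaptor Tyrobp (1.61-fold). Only 1 fell without c-kit-positive replicate 1, and the list's mean of -0.68 became -0.39 without c-kit-negative replicate 1. Of 15 granulocyte and mast cell markers Igsf6 fell (2.62-fold) and the list did not pass (median 0.20, camera adjusted p = 0.787, limma); adjusted over the list alone 2 rose and 1 fell. None fell without c-kit-positive replicate 1 or 3, or c-kit-negative replicate 1 or 2, and 1 rose without either of the last 2. Mean macrophage levels were 6.99, 6.21 and 6.05 in c-kit-negative replicates 1, 2 and 3, and mean platelet levels 6.80, 7.41 and 7.75.

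**Figure D4:**
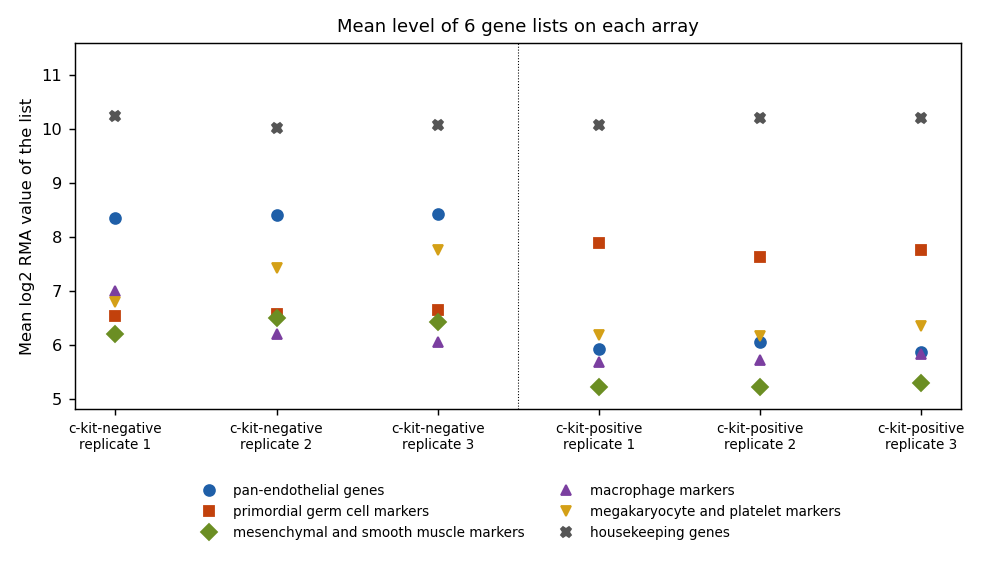
The mean log2 value of the measured genes of 6 lists on each of the 6 arrays, c-kit-negative replicates on the left and c-kit-positive replicates on the right. Pan-endothelial genes stood between 8.36 and 8.42 on the c-kit-negative and between 5.87 and 6.04 on the c-kit-positive arrays, while macrophage and platelet markers also differed among the c-kit-negative arrays.

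Other tissues of the region were followed through their own markers. Of 19 mesenchymal and smooth muscle markers 10 fell, or 13 adjusted over the list alone, and none rose (median -1.07, camera adjusted p = 7.25e-13, limma). Prrx1, a transcription factor of mesenchyme, fell by 2.58 ± 0.20 (log2, SE), and the growth factor receptor Pdgfra was 4.43-fold lower, Twist1 2.94-fold and smooth muscle actin, Acta2, 2.90-fold lower. The falls numbered 6 without c-kit-positive replicate 1. Of 18 mesonephric and gonadal epithelium markers 2 rose and 2 fell, or 3 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.983, limma). The rises were Cdh1, or E-cadherin (2.22-fold), and Epcam (2.15-fold), adhesion molecules that germ cells also carry, and the falls Osr1 (2.52-fold lower) and Podxl (2.37-fold lower). Among 11 neural and neural crest markers Stmn2 was 3.10-fold lower, the only member to pass on either adjustment (median -0.08, camera adjusted p = 0.312, limma). None of 9 hepatoblast markers passed limma's threshold on either adjustment, and 0 had an unadjusted p under 0.05; Apoa1 had the smallest p, at 6.57 ± 0.29 against 6.18 ± 0.17 (SD, n = 3 each).

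Genes of the cell cycle and DNA replication lay slightly higher: 3 of 30 rose, or 5 adjusted over the list alone, and 28 had a positive difference (median 0.28, camera adjusted p = 1.72e-05, limma). The list did not pass with an estimated correlation (adjusted p = 0.14 with an estimated correlation). The rises were Gins1 (2.10-fold) and Chek1 (2.33-fold), which serve replication and its checkpoint, and the mitotic kinase Bub1 (1.64-fold). On the same arrays germ cell markers were higher by a median of 1.13. Of 14 interferon and inflammatory genes none passed limma's threshold on either adjustment and 6 had an unadjusted p under 0.05 (median -0.23, camera adjusted p = 0.0281, limma); the list was lost with an estimated correlation (adjusted p = 0.14 with an estimated correlation). Its member of smallest p, Tlr4, was at 4.28 ± 0.45 against 5.15 ± 0.37 (SD, n = 3 each). The interferon call also ended without c-kit-positive replicate 1 (camera in limma, adjusted p = 0.0553) and without c-kit-negative replicate 1 (adjusted p = 0.118).

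Of 15 immediate early genes, which respond to tissue dissociation, Atf3 fell (3.28-fold) and Nr4a1 rose (1.70-fold), the same on both adjustments, that over all genes and that adjusted over the list alone (median -0.13, camera adjusted p = 0.189, limma). The list passed without c-kit-positive replicate 2 (camera adjusted p = 0.0198, limma). Of 11 housekeeping genes Hprt alone passed, on either adjustment, at 1.78-fold higher; the median was 0.09 and the mean 0.05, while camera pointed down (adjusted p = 0.983, limma). With 1 array left out the housekeeping mean ran from 0.01 to 0.12. Among 4 measured sex-linked genes Xist fell by 2.03-fold on either adjustment, at 7.75 ± 0.34 against 8.77 ± 0.16 (SD, n = 3 each, adjusted p = 0.016, limma), and the 3 Y-linked genes did not pass.

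In all, 14 of the 24 tested lists passed camera with its preset correlation, and 10 with an estimated correlation. Those 10 were the pan-endothelial, arterial, venous and lymphatic, Notch, BMP and TGF-beta, Wnt, basement membrane, imprinted, germ cell and mesenchymal lists. Splits of the 6 arrays other than the labelled one gave 8 to 12 lists with the preset correlation and 0 with the estimated one. Each of these splits still holds part of the population difference, so it is no reference without change. Several small list medians moved by more than 1.5 times with 1 array left out. The Notch median ran from -0.27 to -0.09, Wnt from -0.41 to -0.13, platelet from -0.56 to -0.22 and macrophage from -0.81 to -0.29. Haematopoietic transcription factors ran from 0.14 to 0.22, surface molecules from -0.07 to 0.21, pan-leukocyte genes from -0.08 to 0.15, erythroid markers from 0.03 to 0.17 and granulocyte markers from 0.04 to 0.34. Epithelium markers ran from 0.02 to 0.09, neural markers from -0.15 to 0.05, immediate early genes from -0.27 to 0.07 and housekeeping genes from -0.09 to 0.12. Among the genes named by rule, the calls of Lrrc34, Car1, Dock2, Chek1, Bub1, Tfrc, Ppbp, Pf4, Ctss, Tyrobp, Igsf6, Nr4a1, Hprt and Xist ended when at least 1 array was left out, with adjusted p up to 0.147 (Nr4a1, limma).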

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

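No test in this part was chosen after its result was seen. Of the probe sets outside the gene comparison, some differed between the populations in a fit over all 34760 probe sets (limma, adjusted p under 0.05). Among 1321 probe sets annotated with several genes 23 passed, 8 higher and 15 lower in c-kit-positive cells. Among 11799 probe sets that the annotation table did not list 91 passed, 31 higher and 60 lower. They are given because they carry signal outside the gene-level comparison and enter only the alternative over every probe set; their genes are not named here, and no explanation was tested.

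Splits of the 6 arrays were compared with the labelled one. The labelled split gave 540 higher and 937 lower genes, and the highest count in either direction among the other splits was 0; 1 of the 10 splits, the labelled one, gave as many. For gene lists with camera's preset correlation the labelled split gave 14, and the highest other split gave 12, that of c-kit-negative replicates 1 and 2 with c-kit-positive replicate 2 against the rest; 1 of the 10 splits gave as many as 14. With 10 splits no share under 0.05 can be reached. The other splits gave 8 to 12 lists, and each still holds part of the population difference, so it is no reference without change.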

How the results depend on the processing

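No alternative here was chosen after the data were seen. Stricter thresholds call fewer genes by construction: 215 higher and 615 lower genes with a log2 difference of at least 1, and 131 and 499 at an adjusted p under 0.01. Testing every probe set gave 202 higher and 642 lower, and the linear model without variance moderation, which has fewer degrees of freedom, 66 and 216. Leaving out 1 array gave 276 to 368 higher and 669 to 743 lower genes (fewer samples), and 13 to 15 lists. Without c-kit-negative replicates 1, 2 and 3 the higher genes numbered 276, 292 and 323, and without c-kit-positive replicates 1 and 3 they numbered 311 and 287. The remaining fits of genes gave 476 to 577 higher and 839 to 956 lower. Same-numbered arrays deviated together with correlations of 0.00071, 0.024 and 0.059, and 4 of 6 arrays correlated best with their own number. These values do not settle whether same-numbered samples came from the same sort, which the labels do not say. The replicate block gave 476 higher, 879 lower and 14 lists. No list and no named gene past the threshold changed direction. Ptprc, a named gene that did not pass (-0.24), turned positive without c-kit-negative replicate 1. The interferon list, at a mean of -0.21, did not pass without the dimmest 30 (-0.18) or 50 percent of genes (-0.14) or with an estimated correlation (-0.21), and its mean ran from -0.25 to -0.16 with 1 array left out. With an estimated correlation the cell cycle (0.37), platelet (-1.09) and macrophage (-0.68) lists did not pass either, the last also with fry (-0.68). The mean of the immediate early list ran from -0.25 to -0.0611 with 1 array left out, and it passed without c-kit-positive replicate 2 (-0.25). For these lists the cause was not tested. Of 90 named genes past the threshold, 14 lost it with at least 1 array left out. Nr4a1 also lost it under quantile normalization, an intensity trend with a robust prior, array weights and the replicate block, Nr4a1 and Tyrobp with the probe set of largest SD, and Hprt under the block. Without detection calls, signal over background is unknown for dim genes, and their falls are bounded by the array's background.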

Other observations

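The gene families and single genes of this and the next paragraph, their repeats with 1 array left out, and the tests of germ cells, endothelial cells, array scaling and platelets further on, were chosen after the results were seen. Of 42 measured genes of meiosis and of the defence of the germ line genome, 6 of them also in the germ cell list, 20 rose and none fell in c-kit-positive cells (median 0.78, camera in limma, adjusted p = 2.11e-14). The tudor domain gene Tdrd12 was 3.07-fold and the piRNA pathway gene Mael 3.30-fold higher, and Stag3, a meiotic cohesin, 3.05-fold. The other members did not pass, among them the meiosis genes Stra8 (0.24), Dmc1 (0.43) and Spo11 (-0.0097). Their adjusted p-values were 0.528, 0.513 and 0.982 (limma), so the rise did not extend to all genes of meiosis. Of 37 Hox genes 10 fell and none rose (median -0.38, camera in limma, adjusted p = 2.57e-09), Hoxd8 by 3.63-fold and Hoxc10 by 2.63-fold; with 1 array left out 4 to 6 fell. Of 29 semaphorins and plexins, guidance ligands and receptors, 11 fell and none rose (median -0.31, camera in limma, adjusted p = 1.08e-09). Sema6d was 12.8-fold, Plxnd1 9.46-fold and Sema6a 7.85-fold lower. The median of this family was -0.47 without c-kit-negative replicate 3. Of 26 integrin subunits 7 fell, Itga2 by 7.27-fold and Itga9 by 4.24-fold, and Itga4, the subunit of haematopoietic homing, rose by 1.93-fold (median -0.29, camera in limma, adjusted p = 4.34e-07). The call of Itga4 held only without c-kit-positive replicate 1. Of 12 genes of the insulin-like growth factor axis 7 fell and none rose (median -1.12, camera in limma, adjusted p = 1.85e-09), with Igf1 8.88-fold and Igfbp5 4.62-fold lower beside Igf2 and Igfbp3. These 5 families also passed with an estimated correlation, and their medians kept their sign under median centring and quantile normalization. All families were chosen after the same values were seen, and their p-values were adjusted over the families alone. Neither the p-values nor these repeats are independent support. Of 74 mitochondrial ribosomal protein genes 5 rose (median 0.30), a shift that did not pass with an estimated correlation (adjusted p = 0.078 with an estimated correlation, camera in limma), and with 1 array left out 0 to 4 of them rose. On the same arrays pan-endothelial genes and mesenchymal markers were lower by medians of -2.23 and -1.07, and germ cell markers higher by 1.13.

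Kitl, which encodes the ligand of c-kit, was 7.48-fold lower in c-kit-positive cells, at 3.63 ± 0.20 against 6.53 ± 0.10 (SD, n = 3 each). Zfp57, a zinc finger protein that protects imprints, was 7.83-fold lower (5.63 ± 0.18 against 8.60 ± 0.39). The granulocyte genes S100a8 and S100a9 were 6.61-fold and 9.36-fold lower, and the log2 difference of S100a9, -3.23, became -2.52 without c-kit-positive replicate 1 and -3.91 without replicate 2 of that population. Tdgf1 was 2.71-fold, the noncoding Lncenc1 3.45-fold, Klf5 2.20-fold and the DNA methyltransferase Dnmt3b 2.10-fold higher. All of these passed an adjusted p under 0.05 in limma. Dnmt3b did not pass without c-kit-negative replicate 1 or 3 (adjusted p = 0.0615 and 0.0601, limma), nor S100a9 without c-kit-negative replicate 1 (adjusted p = 0.0517, limma).

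Germ cell markers stood higher in c-kit-positive cells. The tables argue against array scaling that moved all genes alike. The median housekeeping difference was 0.0903 with an SD of 0.36 (-0.09 to 0.12 with 1 array left out), below the 1.13 of the germ cell markers. Housekeeping genes averaged 10.1 and germ cell markers 6.58 in c-kit-negative cells, so a bias that depends on level was not tested. The tables argue also against a lower share of endothelial cells lifting every other type alike, since mesenchymal markers had a median of -1.07. This holds only if the mesenchymal transcripts come from cells other than endothelium, which was not tested. Germ cells in the c-kit-positive gate stay open as a candidate explanation: all 27 markers were higher, which restates the pattern and decides nothing. The 5 of highest mean level, Dppa5a, Rhox9, Dppa3, Utf1 and Pou5f1, all passed (2.20, 2.10, 1.83, 2.64 and 3.41-fold). These 5 also stood high in c-kit-negative cells, at percentiles 98.9, 98.7, 95.6, 92.1 and 83.4 of all genes. Of the 27 markers, 16 lay above the array median in c-kit-negative cells and 22 in c-kit-positive cells. The antibodies to CD45 and Ter119 would not remove germ cells, which carry both CD31 and c-kit. The split by c-kit would place such cells in the c-kit-positive population. It therefore does not account for the high levels of these 5 markers in c-kit-negative cells, whose source was not tested. Expression by progenitors themselves and probes shared with related sequences were not tested.

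Endothelial genes stood lower in c-kit-positive cells. The tables argue against array scaling that moved all genes alike, since the endothelial median was -2.32 relative to that of the housekeeping genes, whose SD was 0.36. Housekeeping genes averaged 10.1 and pan-endothelial genes 8.39 in c-kit-negative cells, so a bias that depends on level was not tested. Fewer endothelial cells in the c-kit-positive gate remain a possible explanation: 25 of 25 genes were lower, which restates the pattern and decides nothing. The 5 of highest mean level in c-kit-negative cells, Cdh5, Emcn, Kdr, Calcrl and Ecscr, all passed (25.7, 25.1, 29.3, 3.48 and 6.47-fold lower). Germ cell and mesenchymal markers moved apart (1.13 and -1.07). Whether fewer endothelial cells were the only change of makeup stays open, since the source of the mesenchymal transcripts was not tested. Lower expression in each endothelial cell was not tested, since pooled RNA gives no value per cell.

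Platelet and globin transcripts differed among the c-kit-negative arrays. Of 14 platelet markers 11 ranked these 3 arrays alike, with replicate 3 highest and replicate 1 lowest, and the 3 embryonic globins ranked them in the same way. These counts restate the pattern and decide nothing, so platelets and primitive red cells in part of the c-kit-negative sorts stay open as a possible explanation; the Ter119 antibody would remove red cells, while platelets carry CD31. Macrophage markers went otherwise, 16 of 18 being highest in replicate 1, as were 30.1% of all genes, and the CD45 antibody would remove macrophages. Ptprc, the CD45 gene, was also highest in replicate 1, at 9.40, 8.66 and 8.21 in replicates 1, 2 and 3. The means of the pan-leukocyte list were 8.04, 7.68 and 7.70. How complete that removal was in each sort was not tested. Differences in embryo pools or dissection between replicates were not tested.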
